A study of Mus musculus with 14 samples.

How the data were processed

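The data were 14 one-colour microarrays of RNA from mouse peritoneal macrophages, 2 arrays in each of 7 groups. Per the labels, the cells were thioglycollate-elicited macrophages of female C57BL/6 mice aged 6 weeks. Total RNA was extracted on silica columns, and 0.5 µg of it was copied to cDNA and transcribed in vitro with biotinylated UTP, with bacterial control RNAs added, per the labels' protocols. The series text states 2 biological replicates for each condition, without saying whether a replicate was 1 animal or a pool of cells. The p-values of the fit without a block measure the spread between these preparations together with the difference between the 2 array sets described below. Each array was placed in its group by its title. The doses, the duration of treatment, the scanner software, the background method and the scaling are not given in the sources used here.

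The deposited value table holds, for each array, 1 linear intensity for each of 10012 probes. The authors had scaled the values before deposit, since each array's median intensity was 1, within rounding (1 array had 1.0007). The method behind that scaling is not stated. At most 0.421% of an array's values were at or below 0, as background subtraction can leave them. No detection calls were used here, so signal over background could be judged only from the level itself. Of the probes, 8983 had 1 gene symbol in the annotation table of the platform, 1 had several and 1028 had none. Only probes with 1 symbol are named. Symbols are those of that table.

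Because the column medians were equal, no further scaling between arrays was applied. Values were raised to a floor at the 5th percentile of all positive values (0.0686, or -3.87 on the log2 scale), and the log2 was taken. A value at the floor is a bound, so a fold change against a group at the floor is a lower limit and is said to be one. Probes were tested where at least 2 of the 14 arrays lay above their own 20th percentile, which kept 9584 probes, 8600 of them with 1 symbol. Group means were fitted to all 14 arrays together in limma 3.58.1 under R 4.3.3, with 7 residual degrees of freedom, and contrasts were tested with moderated statistics and an intensity trend, two-sided. A probe was called where its Benjamini-Hochberg adjusted p over the probes of that comparison was under 0.05. Fold changes are given on the log2 scale with the standard error (SE) of that fit, so +1 is a doubling. Intervals of a difference are the 95% intervals of that fit, without correction for the number of probes. These SEs and intervals also hold the difference between the array sets described below. Each group has n = 2 arrays.

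Gene lists were tested with limma's camera at a preset correlation of 0.01, over 9486 probes with 1 probe for each gene, for 25 lists of at least 5 measured members. These covered inflammatory mediators, interferon-stimulated genes, receptor and pathway targets, metabolism, stress and markers of other cell types. Adjusted p-values are over the lists of a comparison. A camera test with an estimated correlation and the rotation test fry were run beside it. Whether members passed after adjustment over the list alone was counted too. Probes induced by a stimulus were those called at least 2-fold higher than without treatment. Their change with an agonist was set beside 100 simulated agonist groups with no effect, and was tested on the probes induced by the other stimulus, whose arrays do not enter that agonist comparison. In all simulations each probe varied independently of the others. Comparisons that share arrays were set beside simulated unchanged groups and beside the overlap expected of independent lists.

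The arrays fell into 2 sets of 7, here called set A and set B, which split on technical features and not on treatment. The 10th percentile of intensity was 0.137 to 0.271 on the arrays of set A and 0.0549 to 0.0833 on those of set B. Missing values followed the same division: 29 probes were missing on every array of set A and on none of set B, and 30 probes the reverse. Each group had 1 array in each set. If the arrays of a set shared a cell preparation, which is not known, the set difference cannot be told apart from a difference between preparations. The block would then remove that difference too. The first principal component (36.9% of the variance) separated the sets, and the second (27.1%) separated untreated from stimulated cells. An additional fit therefore took the set as a block, with 6 residual degrees of freedom. It gives the same fold changes, and it is called the array-set fit below. Within a group, Spearman correlations between the 2 arrays were 0.929 to 0.966, and the SD of their log2 difference was 0.710 to 1.05.

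In simulated data with the spread of these arrays and known changes in the comparison of GW3965 with LPS against LPS (9584 genes, 10 simulations), the fit without the block called 0.1% of 2-fold and 8.7% of 4-fold changes. The array-set fit called 15% and 75.7%, with 4.39% false calls.

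The genes named in each comparison were chosen by a rule. It took the 10 called genes with the largest increase and the 10 with the largest decrease, where both arrays of a group lay above both of the other. It added a fixed list of anchor genes, called or not, and up to 4 members with the smallest p of each list described. Clone names were left out. The groups, the tests, the floor and the filter, the lists, the naming rule and the first set of alternatives were chosen before the data were examined. Those alternatives were quantile normalization, median centring, other floors and filters, no intensity trend, fits of the compared arrays alone, 1 probe or the mean of probes for a gene, the number in the array titles as a block, and leaving out each array in turn. The array-set fit and its fits with 1 array left out, fits without the array titled GW7845 + poly(I:C) 1, the comparisons pooled over both stimuli, the matching of probes on level and the correlations with crossed array sets were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.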

Results

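Gene expression was measured on 14 microarrays of RNA from mouse peritoneal macrophages, drawn into the peritoneum with thioglycollate, an irritant broth. There were 7 groups of 2 arrays each. One group was untreated, one received LPS (lipopolysaccharide, a bacterial ligand of the receptor TLR4) and one received poly(I:C) (a synthetic double-stranded RNA, a ligand of TLR3). The other 4 groups received LPS or poly(I:C) together with GW3965, an agonist of the liver X receptors (LXRs), or GW7845, an agonist of PPARγ, both of them nuclear receptors that bind lipids. The series title names the differential repression of Toll-like receptor responses by PPARγ and LXRs as its subject. No group received an agonist without a stimulus, so the effect of an agonist alone could not be measured. With n = 2 arrays in a group, the number of arrays limits the precision of every value below. Doses and times are not given in the sources used here, so differences between agonists are differences between the treatments as given. Genes named as called had both arrays of a group beyond both of the other and changed in the same direction in both array sets, while genes that did not pass are named whatever their direction.

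The first question was what LPS changed in these cells. LPS raised inflammatory mediators from near background. Il6, an inflammatory cytokine, rose by 10.88 on the log2 scale (SE 0.46, adjusted p = 1.3e-08), from untreated values of -1.66 and -2.80. Levels that low were not shown to lie above background, so the sizes of such increases, and their order, are approximate. The cytokine Il1b rose by 10.60 (SE 0.73), the interferon-induced chemokine Cxcl10 by 10.51 (SE 0.54) and the interleukin-12 subunit Il12a by 8.72 (SE 0.41). In the other direction, the mRNA of PPARγ itself, Pparg, fell by 4.16 (SE 0.39, adjusted p = 7.8e-06), or 17.9-fold. The lipid-binding protein gene Fabp4, a PPARγ target, fell by 2.03 (SE 0.41, adjusted p = 0.0058). In all, limma called 748 of 9584 probes at an adjusted p under 0.05, 499 higher and 249 lower, and every one of them changed at least 2-fold. The array-set fit called 1702, among them all 748. Without the array titled GW7845 + poly(I:C) 1, described at the end, the count was 820, with 746 of the calls shared. Of the genes named here and below for LPS, Tns1 and Tsc22d3 lost their call when any 1 of the 4 arrays was left out, and Fabp4 without LPS 2 or untreated 1.

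Among the largest increases under LPS were further interferon-stimulated genes, Ifit2 at +8.24 (SE 0.63), Rsad2 at +7.83 (SE 1.12) and Ifit3 at +7.74 (SE 0.45). The pattern-recognition protein Ptx3 rose by at least 7.98 and the prostaglandin synthase Ptgs2 (COX-2) by at least 7.83, where respectively both and 1 of the untreated arrays lay at the floor. The neutrophil attractant Cxcl1 rose by 7.81, Tnf by 7.44, the antiviral GTPase Mx1 by 7.45, the chemokine Ccl5 by 6.47, the monocyte attractant Ccl2 by 6.31 and the inducible nitric oxide synthase Nos2 by 3.36. The receptor for poly(I:C), Tlr3, rose by 3.26 (SE 0.43, adjusted p = 0.00019), while Tlr4 at -0.49 (SE 0.50) did not pass. The largest decreases included the uncharacterised membrane protein gene Tmem273 at -4.80 (SE 0.67), the receptor adaptor Arrb1 at -4.55 (SE 0.47), the lipid phosphatase Lpin1 at -4.32 (SE 0.53) and the mTOR inhibitor Deptor at -4.20 (SE 0.72). Tns1, a focal adhesion gene, was at -4.10, the ubiquitin ligase Fbxo32 at -4.06, Susd3 at -3.91, Ica1 at -3.80 and Tsc22d3, a leucine zipper gene known for its response to glucocorticoids, at -3.66. Cyp27a1, whose product makes the LXR ligand 27-hydroxycholesterol, fell by 2.20. LXR target genes without the agonist did not pass: the sterol transporter Abcg1 was at -0.75 (SE 0.39), the desaturase Scd2 at -1.34 (SE 0.69), and Abca1 at +1.65 (adjusted p = 0.084, or 0.023 in the array-set fit).

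As groups, 10 of the 25 gene lists passed camera under LPS. Of 26 measured interferon-stimulated genes, 24 rose and 2 did not pass, with a median of +4.16 (adjusted p = 1.7e-44, sets A and B +4.19 and +4.34). Adjusted over the list alone, 25 passed. Of 16 inflammatory cytokines 14 rose, with medians of +4.05 and +4.04 in the sets (adjusted p = 1.9e-24), and 14 passed adjusted over the list alone. Of 20 chemokines 15 rose, led by genes such as Ccl7 at +7.53, with a median of +3.24 (adjusted p = 3.4e-23) and 17 adjusted over the list alone. Inflammatory effectors, the enzymes and mediators that act on tissue, rose in 15 of 20 (median +3.18, adjusted p = 6.3e-22, 15 adjusted over the list alone), among them the prostaglandin E synthase Ptges at +6.27 and endothelin, Edn1, at +7.17. NF-kB feedback genes rose in 14 of 16 (median +2.72, adjusted p = 6.1e-20, 15 adjusted over the list alone), such as Traf1 at +4.27, the caspase regulator Cflar at +4.21 and Nfkb2 at +3.92. In the Toll-like receptor pathway 7 of 21 rose (median +1.12, adjusted p = 2.9e-07, 10 adjusted over the list alone), including Tlr2 at +4.24. Of 16 inhibitors of cytokine signalling 7 rose, Socs1 at +5.91 among them, and Sigirr fell by 2.89 (median +1.70, adjusted p = 1.7e-07, 9 up and 1 down adjusted over the list alone). Antigen presentation genes rose in 7 of 20 (median +1.52, adjusted p = 1.2e-08, adjusted p = 0.15 with an estimated correlation, 10 adjusted over the list alone), with Cd40 at +6.78. Oxidative stress genes, 1 of 15 called, had a median of +1.00 (adjusted p = 0.036, adjusted p = 0.54 with an estimated correlation, 3 adjusted over the list alone). PPARγ targets moved down, 3 of 20 called, with a median of -0.37 (adjusted p = 0.0048, sets -0.58 and -0.60, 4 adjusted over the list alone). With an estimated correlation the calls of these lists held except the 2 given, and in the array-set fit that test also ended those of chemokines (0.055), PPARγ targets (0.084) and signalling inhibitors (0.056). Leaving out 1 array ended the calls of PPARγ targets and oxidative stress genes and moved 3 medians by over 1.5 times: PPARγ targets to -0.72 without LPS 1, antigen presentation to +0.68 without untreated 2 and oxidative stress genes to +0.55 without untreated 2. The other 15 lists, LXR targets and markers of other cell types among them, did not pass under LPS or poly(I:C).

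The same question for poly(I:C) gave a closely similar set of genes. Cxcl10 rose by 11.49 (SE 0.54, adjusted p = 1.1e-08), Il6 by 11.14 (SE 0.46, adjusted p = 4.8e-09), Il1b by 10.85 and Il12a by 9.01. Ptx3 rose by at least 8.59, Ifit2 by 8.45, Mx1 by 8.10, Ptgs2 by at least 7.95, Ifit1 by 7.91, Ifit3 by 7.84, Tnf by 7.65, Tlr3 by 3.62 and Nos2 by 3.46. Pparg fell by 3.96 (SE 0.39, adjusted p = 1.1e-05). Also lower were Tmem273 at -4.61, Lpin1 at -4.37, Deptor at -4.29, the stress-response gene Sesn1 at -4.07, the deacetylase Hdac5 at -3.79, Arrb1 at -3.70, the checkpoint kinase Chek2 at -3.65 and Fabp4 at -2.14. limma called 849 probes, 583 higher and 266 lower, against 1791 in the array-set fit and 924 without the array titled GW7845 + poly(I:C) 1. After quantile normalization, which moved the median of all probes by -0.17, the split was 567 higher and 416 lower of 983. Under LPS it moved that median by -0.14 and gave 514 higher and 380 lower of 894. No list that passed under a stimulus changed direction after it, and the small shift of oxidative stress genes lost its call under both.

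The same 10 lists passed under poly(I:C). All 26 interferon-stimulated genes rose (median +4.44, adjusted p = 1.7e-45, 26 adjusted over the list alone), with Mx2 at +7.74. Cytokines rose in 14 of 16 (median +4.42, adjusted p = 1.9e-23, 14 adjusted over the list alone), chemokines in 16 of 20 (median +3.88, adjusted p = 1.9e-23, 17 adjusted over the list alone), effectors in 15 of 20 (median +3.39, adjusted p = 6.0e-22, 15 adjusted over the list alone) and NF-kB feedback genes in 14 of 16 (median +3.31, adjusted p = 5.0e-20, 15 adjusted over the list alone). The Toll-like receptor pathway rose in 9 of 21 (median +1.16, adjusted p = 1.2e-07, 10 adjusted over the list alone), with Irf1 at +3.90. Of the signalling inhibitors 8 rose, with Socs1 at +6.96, and Sigirr fell by 3.22 (median +2.25, adjusted p = 3.7e-08, 10 up and 1 down adjusted over the list alone). Antigen presentation rose in 8 of 20 (median +1.46, adjusted p = 3.1e-08, adjusted p = 0.17 with an estimated correlation, 10 adjusted over the list alone) and oxidative stress genes in 4 of 15, such as the cystine transporter Slc7a11 at +2.97 (median +0.84, adjusted p = 0.023, adjusted p = 0.42 with an estimated correlation, 5 adjusted over the list alone). PPARγ targets fell in 4 of 20 (median -0.42, adjusted p = 0.0026, 4 adjusted over the list alone), among them the fatty-acid oxidation gene Acaa2 by 1.83 (adjusted p = 0.041), and did not pass with an estimated correlation in the array-set fit (0.063). Without untreated 2 the medians moved to -0.67 for PPARγ targets, +0.73 for antigen presentation and +0.24 for oxidative stress genes, whose call ended. Of the genes named, Tsc22d3 lost its call under poly(I:C) too when 1 of 3 of the arrays was left out.

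Compared directly, the stimuli differed in 1 called probe. Ifna7, a type I interferon, was higher under poly(I:C) than under LPS by 4.88 (SE 0.44, adjusted p = 0.00033, sets +5.64 and +4.12), or 29.5-fold. The array-set fit called 2, the other without a gene symbol. An unadjusted p under 0.05 was reached by 52 probes in limma and 301 in the array-set fit, where chance would give 479. In simulated data for GW3965 with LPS, limma called 0.1% of 2-fold and 8.7% of 4-fold changes. The few calls therefore do not show that the stimuli acted alike. Interferon-stimulated genes as a list were slightly higher under poly(I:C) (median +0.28, adjusted p = 3.8e-05, adjusted p = 0.075 with an estimated correlation). B-cell markers were lower, 11 of 12 of them below 0 (median -0.59, adjusted p = 4.2e-06, sets -0.46 and -0.47), and this list also passed with an estimated correlation (adjusted p = 0.022). Markers of T and NK cells had a median of -0.39 (adjusted p = 0.036, adjusted p = 0.78 with an estimated correlation). Each of these 3 lists lost its call when 1 array was left out, the B-cell markers at -0.32 without LPS 2, and the T and NK median crossed 0 (+0.15 without poly(I:C) 2). In the array-set fit the B-cell markers kept their call, at -0.68 to -0.42. Across the 9584 probes the fold changes of the 2 stimuli correlated at r = 0.93, where the shared untreated arrays alone gave a simulated 0.50. The covariance was 1.15 against a simulated 0.0927. Shared calls numbered 472 higher and 190 lower, where independent lists would share 30.4 and 6.91, and part of that excess may come from the shared arrays. Genes are not independent replicates, here or in the correlations below.

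**Figure D1:**
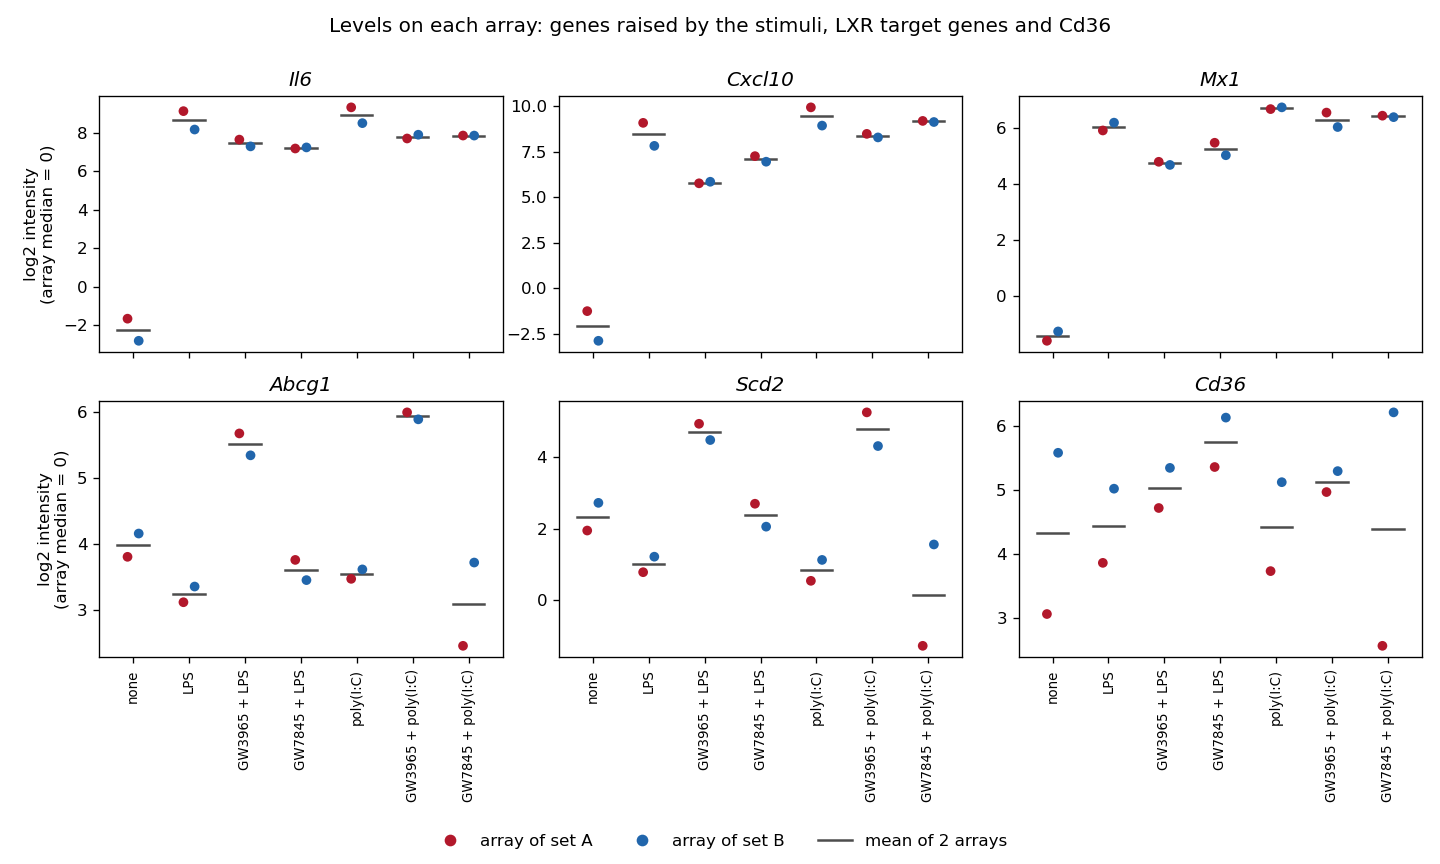
Level of 6 named genes on each of the 14 arrays (y axis: log2 intensity, 0 is the array median), with red points for arrays of set A, blue points for set B and a line at the mean of the 2 arrays of a group. Il6, Cxcl10 and Mx1 rose under LPS by 10.88, 10.51 and 7.45, while Abcg1 and Scd2 were higher with GW3965, under LPS by 2.28 and 3.71.

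The next question was what GW3965 changed in LPS-treated cells. Several LXR targets were higher, and interferon-stimulated genes and some chemokines were lower. Eepd1, an LXR target that keeps the transporter ABCA1 at the cell surface, rose by 2.64 (SE 0.32, adjusted p = 0.011, sets +2.59 and +2.69), or 6.24-fold. Cd5l, an LXR-induced macrophage survival factor, rose by 2.44 (SE 0.35, adjusted p = 0.028, sets +2.40 and +2.48). Slfn4, a Schlafen gene induced by interferon, fell by 2.50 (SE 0.37, adjusted p = 0.028, sets -2.58 and -2.43). These 3 were the calls of limma (298 probes at an unadjusted p under 0.05), and between 0 and 4 probes were called when 1 of the 4 arrays compared was left out, none of the 3 among them, though each kept its direction. Without the array titled GW7845 + poly(I:C) 1 there were 9 calls, the 3 included.

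With the array sets as a block 39 probes were called, 9 higher and 30 lower, the 3 included. The lipogenic genes Scd2 (+3.71, 13.1-fold, adjusted p = 0.026 in that fit), Fasn, the fatty-acid synthase (+2.03, 0.045), and Mid1ip1, an activator of fatty-acid synthesis (+1.76, 0.0068), rose together with the sterol exporter Abcg1 (+2.28, 0.0070). The prostaglandin receptor Ptger2 (+1.58), Cyb5r1 (+1.43) and Tmem86a (+1.37) rose too. Among the decreases were the chemokines Ccl12 (-3.65, adjusted p = 0.0047, sets -4.97 and -2.34), Cxcl10 (-2.64, 0.0066) and Cxcl11 (-2.58, 0.028). Ch25h, which makes 25-hydroxycholesterol, fell by 3.46 (0.039), and the sialic-acid lectin Siglec1 (-2.55, 0.028), the exonuclease Isg20 (-2.39, 0.0021) and Mx1 (-1.31, 0.047) were lower too. The transcription factors Lhx4 (-2.54, 0.0017) and Pou3f1 (-2.24, 0.016) and the cytokine-like Fam3b (-2.43, 0.028) fell as well. The cytokine Il15 fell by 1.44 (0.038). Several genes known as targets of LXR repression did not pass in either fit: Il6 was at -1.18 (SE 0.46), Nos2 at -1.69 (SE 0.41, 0.077 in the array-set fit), Ptgs2 at -1.24, Ccl2 at -1.05, Il1b at -0.21 and Tnf at 0.07 (SE 0.47). Abca1 at +2.12 (SE 0.53) missed the threshold in the array-set fit too (0.077). Leaving out 1 of the 4 arrays moved the count of that fit between 5 without LPS 1 and 104 without GW3965 + LPS 2, with 11 without LPS 2 and 12 without GW3965 + LPS 1. The array titled GW3965 + LPS 1 stood apart from the other 5 stimulated arrays of its set, with 30 probes at least 4-fold below all of them, the most on any array, and 96 bright probes at least 2-fold below, against 1 and 20 on GW3965 + LPS 2.

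Of the 25 lists 11 passed camera in this comparison, and 4 held with an estimated correlation. LXR targets were higher (median +0.69, adjusted p = 6.5e-12, adjusted p = 0.035 with an estimated correlation, sets +0.40 and +1.11). Of 20 measured, 1 rose, 6 passed adjusted over the list alone, and the array-set fit called 4. Interferon-stimulated genes were lower, 23 of 26 below 0 (median -0.83, adjusted p = 3.8e-13, 0.0092 with an estimated correlation, sets -0.81 and -0.86). None was called by limma over all probes, 2 passed adjusted over the list alone, and in the array-set fit these counts were 2 and 13. Inflammatory effectors (median -0.38, adjusted p = 4.5e-05) and the Toll-like receptor pathway (median -0.31, adjusted p = 0.0012) passed narrowly with an estimated correlation (0.049 each). They did not pass that test in the array-set fit (0.069 and 0.054) or without the array titled GW7845 + poly(I:C) 1 (0.086 each), and LXR targets did not pass it without that array (0.059). In the pathway list Tlr3 at -1.60 (SE 0.43) and Ly86 at -1.60 (0.047 in the array-set fit) had the smallest p. Chemokines had a median of -0.67 (adjusted p = 3.8e-09, adjusted p = 0.15 with an estimated correlation, sets -1.08 and -0.30, 3 adjusted over the list alone). Antigen presentation genes were below 0 in 20 of 20 (median -0.64, adjusted p = 1.2e-07, adjusted p = 0.19 with an estimated correlation) and cytokines in 14 of 16 (median -0.60, adjusted p = 2.7e-05, adjusted p = 0.12 with an estimated correlation). Smaller shifts with the same loss under an estimated correlation were those of alternative activation (-0.34, adjusted p = 0.013, then 0.45), glycolysis and hypoxia (-0.27, 0.026, then 0.15), macrophage identity (-0.26, 0.044, then 0.63) and, upward, ER stress (+0.29, 0.026, then 0.15). After quantile normalization glycolysis and macrophage identity no longer passed, and the median of the latter turned above 0. Leaving out LPS 1 or LPS 2 leaves the LPS group on 1 array set, and several medians moved with it: LXR targets to +1.22 and +0.44, chemokines to -0.24 and -1.16, cytokines to -0.26 and -0.92, antigen presentation to -0.30 and -1.11, alternative activation to -0.15 and -1.10 and macrophage identity to -0.0187 and -0.60, while interferon-stimulated genes stayed between -0.82 and -0.67. Effectors moved to -0.24 without LPS 1 and the Toll-like receptor pathway to -0.15 without GW3965 + LPS 2. The calls of the Toll-like receptor pathway, alternative activation, ER stress, glycolysis and macrophage identity ended when 1 array or another was left out. With the array sets as a block, leaving out each of the 4 arrays gave -0.93 to -0.43 for chemokines, -0.80 to -0.44 for cytokines, -0.92 to -0.38 for antigen presentation and +0.40 to +1.08 for LXR targets.

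GW7845 in LPS-treated cells gave no called probe in limma or in the array-set fit, with 138 and 571 probes at an unadjusted p under 0.05 (479 would be so by chance). Chemokines were among the genes with the lowest values. Ccl12 was at -2.42 (SE 0.69), Ccl8 at -2.05 (SE 0.57), Ccl2 at -1.69 (SE 0.52, sets -2.44 and -0.94) and Cxcl9 at -1.36 (SE 0.38). Il6 was at -1.44 (SE 0.46, sets -1.94 and -0.93), Nos2 at -1.39 (SE 0.41), Cxcl10 at -1.35 (SE 0.54) and the transcription factor Klf4 at -1.71 (SE 0.46), while Tnf was at -0.32 (SE 0.47). Of the PPARγ targets none passed: the scavenger receptor Cd36 was at +1.30 (SE 0.98, sets +1.49 and +1.11) and the lipid-droplet coat Plin2 at +0.93 (SE 0.40, sets +1.11 and +0.75), while Fabp4 was at -0.28 (SE 0.41, sets -0.89 and +0.34). In simulated data for GW3965 with LPS the array-set fit called 15% of 2-fold and 75.7% of 4-fold changes, so a change of 2-fold or less could be missed here.

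As lists, 8 passed camera with GW7845 under LPS and none held with an estimated correlation. Chemokines had a median of -0.80 (adjusted p = 4.5e-10, adjusted p = 0.16 with an estimated correlation, sets -1.21 and -0.23, 4 adjusted over the list alone). Antigen presentation genes were below 0 in 20 of 20 (median -0.65, adjusted p = 2.0e-09, then 0.18). Interferon-stimulated genes had a median of -0.36 (adjusted p = 0.00049, then 0.16), cytokines of -0.31 (adjusted p = 0.00021, then 0.16), inhibitors of cytokine signalling of -0.26 (adjusted p = 0.028, then 0.40), alternative activation of -0.23 (adjusted p = 0.028, then 0.51) and the Toll-like receptor pathway of -0.22 (adjusted p = 0.031, then 0.16). PPARγ targets had a median of +0.15 (adjusted p = 0.035, then 0.16), which differed between the sets at -0.05 and +0.38 and did not pass in the array-set fit (0.060). Quantile normalization ended the calls of interferon-stimulated genes, the Toll-like receptor pathway and the signalling inhibitors. Without LPS 1 and without LPS 2, chemokines were at -0.39 and -1.14, cytokines at -0.22 and -0.84, antigen presentation at -0.34 and -1.20 and alternative activation at +0.07 and -0.82. Without GW7845 + LPS 1 the Toll-like receptor pathway was at -0.0587 and the signalling inhibitors at -0.0151. Only chemokines, cytokines and antigen presentation kept their calls whichever array was left out, and with the block the cytokines lost theirs too (-0.53 to -0.26). With the block, leaving out each array gave -1.04 to -0.35 for chemokines, -0.91 to -0.47 for antigen presentation and -0.0379 to +0.30 for PPARγ targets.

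Set against each other under LPS, the agonists differed in LXR targets. With GW7845, Cd5l was lower than with GW3965 by -2.56 (SE 0.35, adjusted p = 0.047, sets -2.33 and -2.79), the only call of limma, lost when any 1 of the 4 arrays was left out, with 155 probes at an unadjusted p under 0.05. The array-set fit called 6, of which 4 had symbols: Eepd1 (-2.06, 0.0046) and Mid1ip1 (-1.63, 0.029) also lower, and Slfn4 higher (+2.23, 0.0047). LXR targets as a list had a median of -1.02 (adjusted p = 2.9e-15, adjusted p = 0.028 with an estimated correlation, 0.052 without the array titled GW7845 + poly(I:C) 1, sets -1.05 and -1.05, 7 adjusted over the list alone). Interferon-stimulated genes were higher with GW7845 than with GW3965 (median +0.36, adjusted p = 2.4e-07, adjusted p = 0.028 with an estimated correlation, 0.075 in the array-set fit, sets +0.40 and +0.38). Effectors (+0.31, adjusted p = 0.017, then 0.25), cholesterol biosynthesis (+0.31, 0.022, then 0.43) and ER stress (-0.41, 0.0074, then 0.14) lost their calls with an estimated correlation and when 1 array was left out. None of these inflammatory genes was shown to differ after correction: the 95% interval of the difference was -1.24 to 0.72 for Il6, -0.58 to 1.18 for Nos2, -1.77 to 0.48 for Ccl2, -1.40 to 0.62 for Tnf and 0.13 to 2.46 for Cxcl10, which excludes 0 only before correction for the number of probes.

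In cells given poly(I:C), GW3965 raised Eepd1 by 2.57 (SE 0.32, adjusted p = 0.015, sets +2.67 and +2.47), the only call of limma, lost in 3 of the 4 fits with 1 array left out, with 143 probes at an unadjusted p under 0.05. With the array sets as a block 7 were called: Scd2 rose by 3.95 (adjusted p = 0.036), Abcg1 by 2.40 (0.014), Cd5l by 1.91 (0.0060), Mid1ip1 by 1.74 (0.015) and Tmem86a by 1.64 (0.044), and 1 probe without a symbol was lower. These 6 higher genes were also higher under LPS, where independent lists of these sizes would share 0.00563. Abca1 was at +2.50 (SE 0.53, 0.094 in the array-set fit). Inflammatory genes lay below 0 without passing, Nos2 at -1.77 (SE 0.41), Il6 at -1.11 (SE 0.46), Cxcl10 at -1.05 (SE 0.54) and Ccl2 at -0.93, and Mx1 was at -0.41 (SE 0.33). Without the array titled GW7845 + poly(I:C) 1 limma called 3 and the array-set fit 13.

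Of 10 lists passing camera with GW3965 under poly(I:C), 2 held with an estimated correlation. LXR targets had a median of +0.22 and a mean of +0.80, since a few members rose far and 8 of 20 lay below 0 (adjusted p = 1.0e-13, 0.022 with an estimated correlation, sets +0.21 and +0.69, 7 adjusted over the list alone). Inflammatory effectors were below 0 in 19 of 20 (median -0.72, adjusted p = 1.1e-08, 0.022 with an estimated correlation, sets -0.74 and -0.73), with Nos2, the metalloprotease Mmp14 (-1.09) and the arginine transporter Slc7a2 (-0.97) among the smallest p, none called over all probes and 1 adjusted over the list alone. Chemokines were below 0 in 20 of 20 (median -0.88, adjusted p = 6.4e-10, adjusted p = 0.17 with an estimated correlation, sets -1.30 and -0.37). The other lists were cytokines (-0.67, adjusted p = 4.9e-05, then 0.17), antigen presentation (-0.58, 6.6e-06, then 0.28), alternative activation (-0.39, 0.016, then 0.37), macrophage identity (-0.36, 0.0059, then 0.37), inhibitors of cytokine signalling (-0.25, 0.037, then 0.37), interferon-stimulated genes (-0.15, 0.024, then 0.26) and ER stress (+0.30, 0.011, then 0.17). Quantile normalization, which moved the median of all probes by 0.11 here, ended the calls of interferon-stimulated genes, signalling inhibitors and macrophage identity. Leaving out poly(I:C) 1 or poly(I:C) 2 moved LXR targets to +0.66 and -0.0093, chemokines to -0.49 and -1.20, cytokines to -0.34 and -0.89, antigen presentation to -0.20 and -1.02 and ER stress to +0.49 and -0.0263. It also moved alternative activation to +0.0034 and -0.92 and macrophage identity to -0.0936 and -0.70. The signalling inhibitors were at +0.0031 without GW3965 + poly(I:C) 2. Interferon-stimulated genes ranged from -0.373 to -0.0364 when 1 array was left out, and their test turned in direction without poly(I:C) 2. Only LXR targets, effectors, chemokines and antigen presentation kept their calls whichever array was left out. With the block, leaving out each array gave +0.13 to +0.73 for LXR targets, -1.12 to -0.55 for chemokines and -0.73 to -0.61 for effectors.

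GW7845 in cells given poly(I:C) gave no call in limma or the array-set fit, with 83 and 363 probes at an unadjusted p under 0.05. Its values rested on 2 arrays that differed, since the array titled GW7845 + poly(I:C) 1 stood apart from the others. The growth factor Csf2 was at -2.54 (SE 0.77, sets -4.70 and -0.39), the activin subunit Inhba at -2.38 (SE 0.70, sets -4.20 and -0.56), Ptgs2 at -2.14 (SE 0.75, sets -3.60 and -0.68), the transcription factor Irf8 at -1.86 (SE 0.61, sets -2.91 and -0.81) and Il1b at -1.50 (SE 0.73, sets -2.98 and -0.03). Il12a was at -1.44 (SE 0.41, sets -1.96 and -0.92), Il6 at -1.06 (SE 0.46, sets -1.46 and -0.65) and Nos2 at -1.49 and -0.50 in the sets. Of PPARγ targets, Fabp4 was at +0.81 (SE 0.41, sets +0.96 and +0.66), and Cd36 went opposite ways in the sets (-1.16 and +1.09). Without GW7845 + poly(I:C) 2 instead, limma called 28 probes and the array-set fit 99.

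Of the 12 lists that passed camera here, none held with an estimated correlation. Cytokines had a median of -0.69 (adjusted p = 1.1e-09, then 0.091, 3 adjusted over the list alone) and did not pass without the array titled 1 (median -0.42, 0.079). Chemokines (-0.49, 4.1e-08, then 0.13) and antigen presentation (-0.29, 4.9e-09, then 0.13) passed without it, at medians of -0.57 (0.0048, then 0.61) and -0.59 (0.016, then 0.61). PPARγ targets were higher, 14 of 20 above 0 (median +0.21, adjusted p = 0.0086, then 0.091, sets +0.15 and +0.34), and without that array stood at +0.23 (3.7e-05, then 0.048). The lists of NF-kB feedback (-0.31, 0.00071, then 0.10), effectors (-0.29, 6.0e-05, then 0.091), the Toll-like receptor pathway (-0.09, 0.017, then 0.10), inhibitors of cytokine signalling (-0.34, 0.00095, then 0.13), glycolysis and hypoxia (-0.24, 0.00095, then 0.091), alternative activation (-0.37, 0.0020, then 0.28) and dendritic cells (-0.39, 0.019, then 0.10) passed only with it. Cholesterol biosynthesis had a median of -0.19 (0.038, then 0.40) and turned to +0.36 without it (0.0048, then 0.13). The chemokine median was +0.0266 without poly(I:C) 1 and -0.85 without poly(I:C) 2, and -0.68 to -0.24 with the block on leaving out each array. Chemokines and antigen presentation alone kept their calls whichever array was left out, and PPARγ targets lost theirs without poly(I:C) 1 or GW7845 + poly(I:C) 2, the latter with the direction of their test turned.

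Between the agonists under poly(I:C), several LXR targets differed. With GW7845, Scd2 was lower than with GW3965 by -4.64 (SE 0.69, adjusted p = 0.025, sets -6.53 and -2.75), Abcg1 by -2.86 (SE 0.39, adjusted p = 0.019), Cd5l by -2.52 (SE 0.35, adjusted p = 0.019) and Eepd1 by -2.28 (SE 0.32, adjusted p = 0.019). These were the 4 calls of limma, with 190 probes at an unadjusted p under 0.05, and none of them was called without the array titled GW7845 + poly(I:C) 1 or without either array of GW3965 + poly(I:C). With the sets as a block 10 were called, with Abca1 (-2.92, 0.020), Fasn (-2.54, 0.020) and Mid1ip1 (-2.10, 0.0018) lower and the X-inactivation transcript Xist (+1.70, 0.033, sets +1.97 and +1.44) higher, and 12 without that array, 7 of them shared. LXR targets had a median of -0.20 and a mean of -0.81 (adjusted p = 1.1e-12, adjusted p = 0.055 with an estimated correlation, 0.018 in the array-set fit, 5 adjusted over the list alone). That median was -0.95 without GW7845 + poly(I:C) 1 and +0.13 without GW3965 + poly(I:C) 1, against -0.56 to -0.19 with the block. ER stress had a median of -0.29 (0.013, then 0.21) and lost its call when 1 array was left out. Without GW7845 + poly(I:C) 1 further lists passed camera, all higher with GW7845: effectors (+0.30, 1.5e-05), interferon-stimulated genes (+0.34, 0.00013), PPARγ targets (+0.38, 0.0010), cholesterol biosynthesis (+0.51, 2.5e-05), chemokines (+0.19, 0.039) and neutrophil markers (+0.41, 0.016), and none of them passed with an estimated correlation. All probes had a median of +0.14 in this comparison, which quantile normalization moved by -0.14. The 95% interval of the difference was -0.92 to 1.03 for Il6, -0.10 to 1.65 for Nos2, -1.13 to 1.11 for Ccl2, -1.75 to 0.27 for Tnf and -0.38 to 1.94 for Cxcl10, so none of these was shown to differ.

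Whether an agonist acted differently under the 2 stimuli was tested as a difference of differences. No probe was called for either agonist by limma (29 probes for GW3965 and 46 for GW7845 at an unadjusted p under 0.05) or by the array-set fit (274 and 281). For GW3965 the interferon-stimulated genes passed as a list, with a median of -0.46 (adjusted p = 1.1e-08, 0.031 with an estimated correlation, 0.11 for that test in the array-set fit), lower under LPS than under poly(I:C). Its call ended without LPS 2 or poly(I:C) 1, and the median ranged from -0.72 to -0.32 when 1 array was left out. Cxcl10 was at -1.59 (SE 0.76), Tlr3 at -1.53 (SE 0.61) and Mx1 at -0.90 (SE 0.47), none of them called. The same list lay at -0.33 for GW7845, measured against the same LPS and poly(I:C) arrays, and did not pass (0.32). For GW7845 cholesterol biosynthesis passed with a median of +0.47 (adjusted p = 0.015, adjusted p = 1.0 with an estimated correlation), which was -0.02 without the array titled GW7845 + poly(I:C) 1.

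The genes that a stimulus had induced were also followed as a set. Of the 499 probes at least 2-fold higher under LPS, 80.8% were lower with GW3965 than with LPS alone (median -0.44) and 80.2% were lower with GW7845 (median -0.30). Of the 583 induced by poly(I:C), 83.7% were lower with GW3965 (median -0.39) and 73.9% with GW7845 (median -0.20). Under each stimulus both agonists were set against the same arrays of the stimulus alone. High values on those arrays would lower both results, so the results of the agonists are not independent. Simulated groups with no effect, which also show regression since these probes were picked for high values, gave at most 61.3%, 63.1%, 61.6% and 60.9%. At least 2-fold lower were 91, 46, 56 and 34 probes, against at most 16, 15, 17 and 18 in the simulations. The simulated arrays carried a fixed difference between the array sets. Their probes varied independently, so genes that move together were not imitated, and these ranges are too narrow. Random probes, not induced, were matched on level to the probes that the other stimulus had induced. Their medians were -0.12 for GW7845 under LPS and -0.11 for GW3965 under poly(I:C). The lowest simulated medians, over probes induced by the same stimulus, were -0.12 and -0.0853. The medians in sets A and B were -0.48 and -0.41, -0.38 and -0.30, -0.40 and -0.38, and -0.30 and -0.07, in the same order, and the last value lies within its simulated range of -0.0867 to -0.0151. Single probes rarely passed: limma called 1 of the LPS-induced probes lower with GW3965 and 0 in the other 3 cases, and the array-set fit called 25 of 844 so for GW3965 under LPS and 0 elsewhere. The counts at an unadjusted p under 0.05 are those given for each comparison.

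Picking the probes by the other stimulus, whose arrays do not enter the agonist comparison, gave medians of -0.42 for GW3965 and -0.28 for GW7845 under LPS, and -0.37 and -0.19 under poly(I:C). By camera with an estimated correlation the adjusted p-values were 0.0072, 0.012, 0.010 and 0.012. Random probes matched on level had medians of -0.08, -0.12, -0.11 and 0.00. Quantile normalization brought the medians to -0.30, -0.14, -0.19 and -0.16. Without the array titled GW7845 + poly(I:C) 1 the last of the 4 was -0.14 and did not pass (0.84). Between the agonists, the probes induced by the same stimulus were compared. Under LPS the LPS-induced probes were a little higher with GW7845 than with GW3965 (+0.12, camera adjusted p = 1.0e-06, adjusted p = 0.053 with an estimated correlation). Under poly(I:C) the difference over the poly(I:C)-induced probes was +0.17, where all probes had a median of +0.14, and did not pass camera (0.051). Without the array titled GW7845 + poly(I:C) 1 it was +0.21 (camera 5.9e-13, then 0.022 with an estimated correlation).

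**Figure D2:**
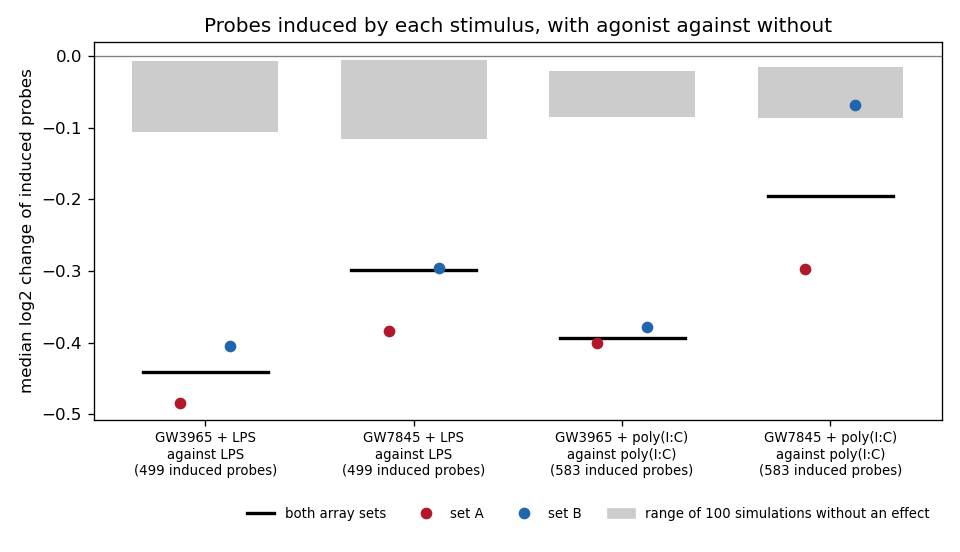
Median log2 change with each agonist over the probes that the stimulus had induced (y axis), with a line for both array sets, points for set A and set B, and grey for the range of 100 simulations with no effect. The medians were -0.44 and -0.30 under LPS and -0.39 and -0.20 under poly(I:C), for GW3965 and GW7845, each below its simulated range. That range is too narrow, since the simulated probes varied independently.

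Across all 9584 probes the changes with GW3965 under LPS and under poly(I:C), which share no array, correlated at r = 0.34. Simulated groups with no effect, whose probes varied independently, gave at most 0.03. For GW7845 the value was 0.10 against at most 0.04, and 0.20 without the array titled GW7845 + poly(I:C) 1. Taking LPS from one array set and poly(I:C) from the other, r was 0.07 and 0.12 for GW3965 and 0.05 and 0.05 for GW7845, and with both from the same set 0.32 and 0.20, and 0.03 and 0.14. The GW3965 values were lower with the sets crossed, and none of these single-array values has a simulated counterpart. Between the agonists, which share the arrays of the stimulus, r was 0.58 under LPS against a simulated 0.50 (covariance 0.160 against 0.0934) and 0.36 under poly(I:C) against 0.50 (0.0747 against 0.0934), or 0.48 without that array.

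The array titled GW7845 + poly(I:C) 1, of set A, differed from the other stimulated arrays of its set. On it 28 probes were at least 4-fold above and 9 at least 4-fold below all 5 others. Tsc22d3 was at 6.88 on the log2 scale where the others averaged 3.27, the chitinase-like Chil3 at 8.30 against 4.01, the metallothionein Mt2 at 5.87 against 1.59, the glutamine synthetase Glul at 6.25 against 2.90 and the phosphatase Dusp1 at 5.59 against 2.78. Csf2 was at -1.50 against 2.35, Ptgs2 at 0.31 against 3.57, Irf8 at -0.10 against 2.84, Il1a at 5.23 against 8.41 and the receptor Clec7a at 2.41 against 6.05. These genes were picked after their values were seen. The untreated array of set A had Tsc22d3 at 6.49, Glul at 4.70, Csf2 at -2.71 and Ptgs2 at the floor. On the array titled GW7845 + poly(I:C) 1, Tsc22d3, Csf2 and Ptgs2 thus lay toward the untreated level, while Glul lay above that level too. Mt2, Chil3, Dusp1 and Clec7a did not lie toward it (untreated Chil3 was at 4.20, Dusp1 at 2.02 and Clec7a at 6.24), and Irf8 lay below its untreated level of 1.74. Of the 28 probes, 22 were at least 4-fold above the untreated array as well. The other 11 stimulated arrays had 1 to 22 probes above and 0 to 30 below in the same measure, the 22 on LPS 2 and the 30 on GW3965 + LPS 1.

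**Figure D3:**
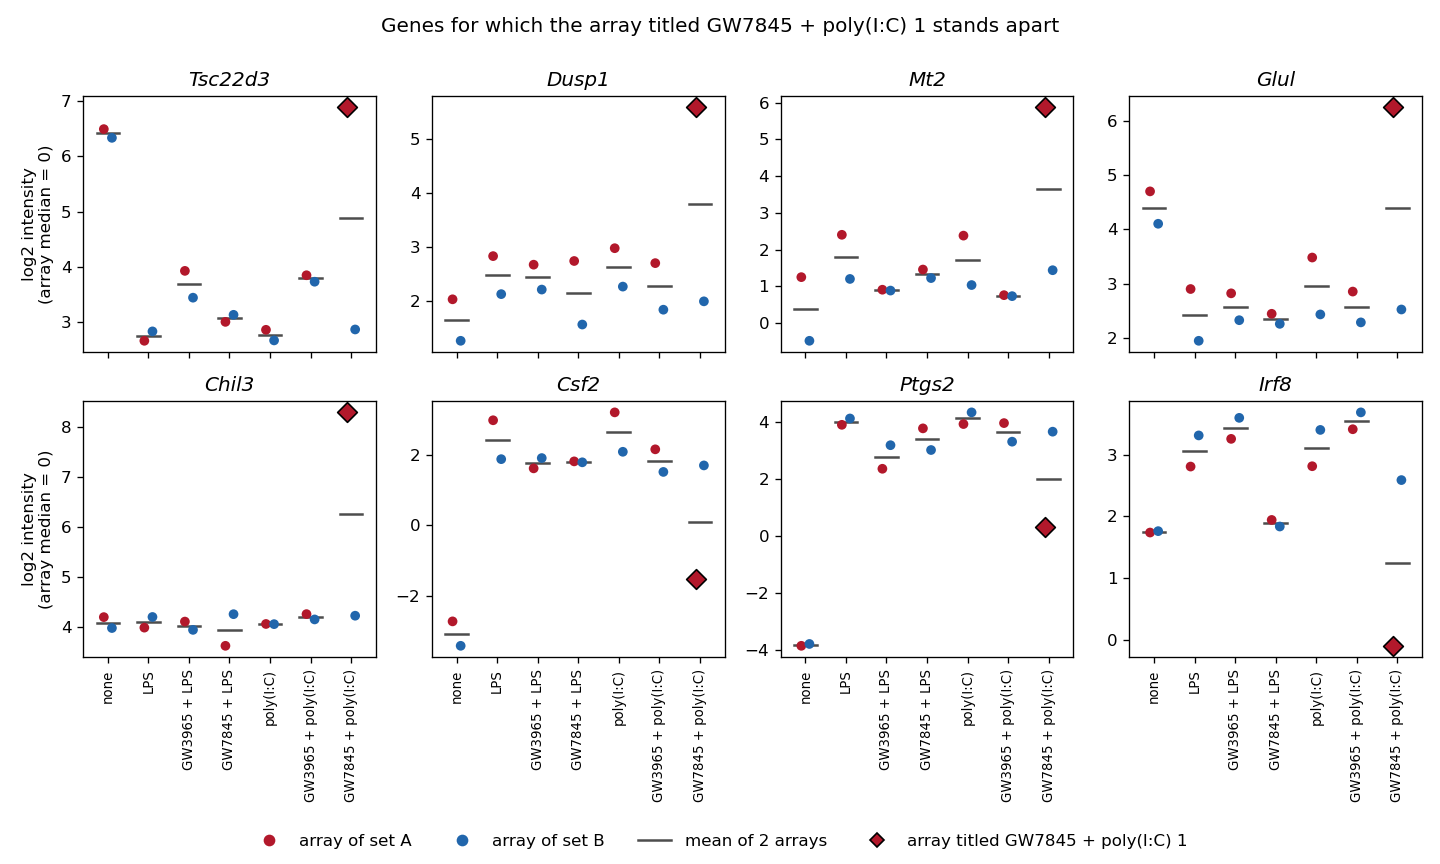
Log2 level of genes that differed on the array titled GW7845 + poly(I:C) 1, shown for that array, the other stimulated arrays and the untreated arrays, with array sets by colour. Tsc22d3 stood at 6.88 on that array against a mean of 3.27 on the other stimulated arrays of set A, and Csf2 at -1.50 against 2.35.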

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

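Of the tests below, the array-set fit and the values without the array titled GW7845 + poly(I:C) 1 were chosen only after the results were seen, and the spread of the medians was brought into the reading of 2 tests (the dimmer genes and the markers of other cell types) after their values were known.

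GW3965 lowered interferon-stimulated genes more under LPS than under poly(I:C), and this list stood out because the difference between the stimuli passed its own test (median -0.46, 26 genes, camera adjusted p = 1.1e-08). The difference was not that of a single array set, since the median was -0.46 in set B, where it was closest to 0, and -0.65 in set A, with 21 and 20 of the 26 genes below 0. A second technical account, compression of bright signals under poly(I:C), needs the dimmer genes to differ less, and their median was -0.32 (SE 0.27) against -0.50 (SE 0.13) for the brighter ones, with the limit set at -0.3, so the spread of the dimmer genes keeps it open. The genes move together, and with their correlation estimated the list passed at 0.031, but not in the array-set fit (0.11), not without the array titled GW7845 + poly(I:C) 1 (0.060), and not by the rotation test fry (0.77), and leaving out 1 array ended even the first call (without LPS 2 or poly(I:C) 1), with medians of -0.72 to -0.32. A stimulus-specific action of the LXR agonist therefore stays a hypothesis, since GW7845, set against the same LPS and poly(I:C) arrays, lay the same way (-0.33, 0.32, and without that array -0.38, 4.1e-05, then 0.24), and unequal doses or times of the stimuli, which the labels do not give, stay open and untested.

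For GW7845, cholesterol biosynthesis genes differed between the stimuli (difference +0.47, 13 genes, camera adjusted p = 0.015), which is why they are listed here. The difference rested on a single array: it was +1.19 in set A, -0.07 in set B, and -0.02 without the array titled GW7845 + poly(I:C) 1.

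That array stood apart in a way its label does not give, with 28 probes at least 4-fold above the other 5 stimulated arrays of its set, among them Tsc22d3, Mt2, Glul and Dusp1. A glucocorticoid in the culture was a candidate explanation, named after many such genes had been looked at (Fkbp5, Klf9 and Sik1 high too, Per1, Sgk1, Errfi1 and Cd163 not clearly raised), and the list of glucocorticoid-induced genes not looked at before had a median of only +0.27 (SE 0.12, 17 genes), no more than the +0.29 of the array titled poly(I:C) 1, and between the limits of 0.2 and 0.5 set for it. Cells of another type could raise their own transcripts, and the highest median among 5 marker lists was 0.37 (SE 0.14) for fibroblasts and mesothelium, under the limit of 0.5 but within its spread. All probes had a median of +0.14 on that array in the same measure, so part of both list medians is not particular to these lists. An exchange of stimulus labels between the GW7845 arrays of set A is argued against by a correlation of 0.14 with the poly(I:C) minus LPS difference of other arrays, where an exchange needs a negative value. A weaker response to the stimulus (untreated Tsc22d3 was 6.49), which leaves unexplained the 22 of the 28 probes that were 4-fold above the untreated array too, a swap with a sample from outside the series, or another treatment, was not tested further and stays open. The 583 probes induced by poly(I:C) had a median of -0.30 with GW7845 in set A, where GW3965 had -0.40. A weaker response of the induced genes as a set is thus not shown.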

How the results depend on the processing

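The array-set fit, its combinations and the fits of that model with 1 array left out were chosen only after the data had been seen. The precision is limited by 2 arrays in a group and by signals near background, where a value at the floor is a bound. Across the alternatives 226 counts stayed within 1.5 times and 109 moved beyond it. Of the values of named genes, 5429 kept their direction and side of the threshold, 63 lost and 90 gained a call, 240 moved without a call at stake, and none changed direction. Of the values of lists, 863 were kept, 265 lost their call, 8 gained one and 5 reversed. An estimated correlation ended 47 of them, fry 51, leaving out 1 array 148 and quantile normalization 15. For the values below the cause was not tested, except that a fit of fewer arrays estimates the spread from fewer of them.

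With the array sets as a block, calls were 1702 for LPS and 1791 for poly(I:C) against no treatment, 39 for GW3965 under LPS (25 of them LPS-induced and lower) and 7 under poly(I:C), 6 between the agonists under LPS and 10 under poly(I:C), and 2 between the stimuli. Between the agonists under LPS this fit gave 10 with a filter at the 50th percentile and 15 with quantile normalization. Quantile normalization alone gave 10 for GW3965 under LPS (6 LPS-induced and lower) and 3 under poly(I:C). With the floor at the 20th percentile GW3965 under LPS had 5 (3 LPS-induced and lower). Between the agonists under LPS there were 0 with no floor and 2 with the filter at the 50th percentile. Without an intensity trend, GW3965 under either stimulus and the agonist contrasts had 0 calls, as had the LPS-induced genes with GW3965. Fits of only the arrays compared gave 410 for LPS, 457 for poly(I:C), 61 for GW3965 under LPS (23 LPS-induced and lower), 3 for GW7845 under LPS (1), 4 for GW3965 under poly(I:C) (1), and 50 and 2 between the agonists under LPS and poly(I:C).

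The title numbers were tried as a replicate block. In 6 of the 7 groups number 1 was the array of set A, and their differences between numbers correlated at 0.35 to 0.67, while GW7845 + LPS ran opposite (-0.54 to -0.39). Whether its titles were exchanged is open, so the numbers were not taken as pairs. This fit gave 13 for GW3965 under LPS (8 LPS-induced and lower), 3 under poly(I:C), 4 and 8 between the agonists under LPS and poly(I:C), and 2 between the stimuli.

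Leaving out each array in turn, with a lone array assumed to vary like the other groups, gave these lowest and highest counts, first without and then with the array sets as a block. LPS had 467 (without LPS 2) to 820 and 931 to 1782. Poly(I:C) had 548 (without poly(I:C) 1) to 924 and 1088 to 1871. GW3965 under LPS had 0 to 9 and 5 to 104, and under poly(I:C) 0 to 3 and 0 to 13. GW7845 under poly(I:C) had 0 to 28 and 0 to 99, both highest without GW7845 + poly(I:C) 2, and under LPS 0 to 3 with the block (highest without GW7845 + LPS 2). Between the agonists there were 0 to 5 and 2 to 48 under LPS (highest of the first without GW3965 + LPS 2), and 0 to 42 and 5 to 98 under poly(I:C), where 42 came without GW7845 + poly(I:C) 2. Between the stimuli there were 1 to 2 and 1 to 5. The interaction had 0 to 14 with the block for GW3965 (highest without GW3965 + LPS 2), and 0 to 9 and 0 to 41 for GW7845 (highest without GW7845 + poly(I:C) 2). LPS-induced genes lower with GW3965 numbered 0 to 4, poly(I:C)-induced ones 0 to 2 with GW3965 and 0 to 10 with GW7845.

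When 1 array was left out, 4 of the 75 list results turned in the direction of their test, and the median of 13 crossed 0, where the array sets are no longer balanced. With the sets as a block 1 turned and 4 crossed 0. Interferon-stimulated genes with GW3965 under poly(I:C) ranged from -0.373 to -0.0364 and turned in test direction without poly(I:C) 2 (-0.08). PPARγ targets with GW7845 under poly(I:C) ranged from 0.14 to 0.37 and turned in test direction without GW7845 + poly(I:C) 2 (0.14). Cholesterol biosynthesis ranged from -0.76 to 0.36 with GW7845 under poly(I:C), with 0.36 without GW7845 + poly(I:C) 1 (with the block from -0.71 to 0.27, the latter without that array), and from -0.0179 to 1.18 in the interaction, with -0.0179 without that array. The correlation of GW3965 changes under the 2 stimuli was 0.64 with the filter at the 50th percentile.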

Other observations

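The tests of GW7845 under each stimulus alone and the comparisons pooled over both stimuli were chosen only after the results were seen.

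Pooling both stimuli sets 4 GW3965 arrays against 4 arrays of the stimulus alone, with stimulus and array set as blocks. limma called 140 probes, 36 higher and 104 lower. The genes Scd2 (+3.83), Eepd1 (+2.61), Abcg1 (+2.34) and Abca1 (+2.31) were higher on 4 of 4 pairs, and Nos2 (-1.73) and the 25-hydroxycholesterol enzyme Ch25h (-3.19) were lower, so genes that LXR agonists act on, Abca1 and Nos2 and also Il6 (-1.14) and Ccl2 (-0.99), were called here and not under either stimulus alone. Of the 104 lower probes, 61 were among those induced by LPS, which were 499 of all 9584 probes. Those probes were picked for high values on LPS arrays that also enter this comparison, so part of that number may come from the choice. Only 1 of the 33 splits of these 8 arrays, the real one, gave as many calls (highest other 0), but most of them break up the stimuli or array sets, and the 8 that swap arrays within a stimulus and set, where the highest other was 0 too, are too few for a share under 0.05. The count ranged from 27 (without GW3965 + poly(I:C) 1) to 210 when 1 array was left out.

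The same pooling for GW7845 called 1 probe, which has no gene symbol, while 3 of the 33 splits called at least as many and the highest of the others called 85. Chance cannot be excluded for that call. The split with 85 calls set LPS 1, LPS 2, GW7845 + LPS 1 and the odd array GW7845 + poly(I:C) 1 on one side, and why it gave so many was not tested. Its sides are LPS and poly(I:C) as an exchange of the stimulus labels of the set A GW7845 arrays would give them. The correlation of 0.14 given above argues against that exchange.

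Why GW7845 gave no call was weighed among 2 accounts. The number of arrays fits: the array-set fit called 15% of simulated 2-fold changes, so changes of that size could pass unseen. An absent effect of the compound was tested by the correlation of its changes under the 2 stimuli, which was 0.10, above the highest of 0.04 in simulations. The simulated probes varied independently, which makes that range too narrow, so that test excludes nothing. Under LPS the genes induced by poly(I:C) were lower with an adjusted p of 0.021 by camera with an estimated correlation, without the array titled GW7845 + poly(I:C) 1. That array enters this comparison only through the estimate of spread, and the LPS arrays, which do enter it, were kept. The median was -0.28, or -0.14 after quantile normalization, and random probes matched on level had -0.12 before that normalization. The lowest of 1000 such matched lists, also before it, had -0.17. The camera test did not match probes on level, and no matched median was computed after that normalization. These values therefore do not decide whether an effect under LPS is absent. Under poly(I:C) the median of the LPS-induced genes without that array was -0.14, which did not pass (0.84), so an effect there stays open. Whether a weak, broad lowering of induced genes by GW7845 under LPS is a real effect, too small to call gene by gene with 2 arrays, was not settled.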
